A study of Mus musculus with 6 samples.

How the data were processed

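RNA sequencing had been done on 6 libraries of neurospheres from mouse hippocampus, 3 labelled WT and 3 labelled cKO for Slc22a17. Total RNA had been extracted with a column kit for lipid-rich tissue and the libraries had been sequenced and processed by a BGISEQ service, per the labels' protocols. The deposited values are FPKM, fragment counts scaled to transcript length and to the mapped fragments of the library, 1 value per gene and library, per the file headers. Bowtie2 and the mouse genome build GRCm38 (mm10) are named in the submitters' processing notes, without a version of the aligner. The counting tool, the annotation, the transcript lengths used and any filter are not given in the sources used here.

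The table held 14327 genes with a symbol and a numeric gene identifier, and 6 columns of values with 2 decimals. No value was 0 and the lowest was 0.01. Of the identifiers 14317 were found in the RefSeq annotation of GRCm38.p6, which gave chromosome, start, end and gene type, and 14292 were protein-coding. The table held no mitochondrially encoded gene. Each column name matched 1 sample by its group and number. Reads from genes that overlap or have near-identical copies cannot be told apart in such a table.

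FPKM values carry no depth. Low values of genes with annotated transcripts of 300 to 1500 bases were searched for steps worth 1 fragment, which gave estimates of 16850000 to 17400000 fragments per library. From 44 to 55 values were used per library. The search covered a limited range of depths, since a multiple of the true depth also gives whole steps. A depth outside that range could not have been found. With a tolerance of 0.1 fragment, 43.1% to 56.9% of the low values used were whole. At a depth fixed beforehand 20% would be expected by chance. The depth was chosen to fit these same values, so the share expected by chance is higher than that. Whole reads were therefore not recovered and no count model was run. In WT replicate 1, 3 of 100 shuffles gave a fit as good, and in the other libraries 0 of 100. The depth estimates differed by 3.26% between libraries. Precision was taken from the spread between libraries.

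Values were analysed as log2(FPKM + 1) for the 11596 genes with a mean of at least 1 FPKM over all 6 libraries, and 2731 genes were left out. A fold change on this scale understates the change of genes with low values. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Slc22a17 was also compared by an exact permutation test of its 6 FPKM values. Gene groups were 32 lists with 1016 entries written from general knowledge, of which 914 entries were in the table, 4 of them through a synonym. The 29 lists with at least 5 tested members were compared by limma's camera with a preset correlation of 0.01, adjusted over these lists. Beside camera stand an estimated correlation between the genes of a list, the self-contained test fry, and the number of members past the threshold adjusted over all genes and adjusted over the list alone. The design, the alternatives and the lists were fixed before the data were examined.

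Genes named are Slc22a17, genes past the threshold with non-overlapping groups (at most 12 each way), or, where fewer than 5 passed in a direction, the 5 genes of lowest p in it, protein-coding and with an assigned symbol. Added to these are 2 to 4 members of lowest p of each list described, and 13 genes chosen in advance: Tfrc, Fth1, Ftl1, Slc40a1, Lcn2, Nes, Sox2, Dcx, Tubb3, Gfap, Gpx4, Slc7a11 and Mki67. Exceptions to this rule are stated where they occur.

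The gene tests were tested on simulated data for the 11596 genes, with the means and spreads of the real libraries and 200 changed genes in each of 20 runs. The limma fit found 76.0% of genes changed 1.5-fold, 94.1% of those changed 2-fold and 98.9% of those changed 3-fold, and called 12.7 unchanged genes per run on average. With 200 changed genes in a run the adjustment is milder than with the few calls of the real data. These shares are therefore not the chance of a call in the real comparison. There Hopx, at 3.03 times the WT mean, did not pass in limma (adjusted p = 0.103). The simulated genes varied independently of each other, so these runs do not test the list tests for genes that vary together.

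Alternatives tried were other pseudocounts, other filters, between-library scaling, other variance models, library weights, the replicate number as a block, leaving out each library, other thresholds and other set tests. After the Y-linked transcripts had been seen, 3 more were added: the Y-linked share as a covariate (Ddx3y plus Eif2s3y relative to the mean of the libraries labelled cKO), leaving out WT replicates 1 and 2, and leaving out genes on the X and Y chromosomes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.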

Results

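RNA was sequenced from 6 libraries of mouse neurospheres, floating cultures of neural stem and progenitor cells grown from the hippocampus at postnatal day 0 in medium with EGF and bFGF. There were 3 libraries from wild-type (WT) mice and 3 from mice labelled as conditional knockouts (cKO) of Slc22a17, which encodes a cell surface receptor for the iron-carrying protein lipocalin 2. The table held FPKM values for 14327 genes, of which 11596 had a mean of at least 1 FPKM and were tested. FPKM carries no read totals. The steps between the lowest values, searched over a limited range of depths, gave a rough estimate of 16850000 to 17400000 fragments per library. The highest and the lowest library differed by 3.26%. The labels do not say whether the libraries of a group came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.

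The libraries differed in transcripts of the Y chromosome. Ddx3y and Eif2s3y, which are expressed from the Y chromosome in male cells, together reached 0.10 and 0.07 FPKM in WT replicates 1 and 2, 25.9 FPKM in WT replicate 3, and 50.5, 43.8 and 51.2 FPKM in the libraries labelled cKO. WT replicate 3 therefore stood at 53.4% of the mean of the libraries labelled cKO. Uba1y, the other Y-linked gene in the table, was low in all libraries and did not follow this pattern as closely. It stood at 0.49, 0.44 and 0.89 FPKM in WT and at 1.07, 0.96 and 0.86 FPKM in the libraries labelled cKO. Eif2s3x, the X-linked partner of Eif2s3y, was at 110, 114 and 90.0 FPKM in WT and at 72.0, 72.8 and 72.2 FPKM in the libraries labelled cKO (log2 fold change -0.52, adjusted p = 0.126). The labels do not give the sex of the mice, and group and Y-linked share could not be separated in this design. Eif2s3x was chosen after its values were seen.

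The comparison of the groups asks what loss of Slc22a17 changes in hippocampal neural stem cells, with iron balance and the formation of neurons as the processes named by the study. The transcript of Slc22a17 itself (gene identifier 59049, chromosome 14, 54906727 to 54913132 in GRCm38) was abundant in every library. It was at 181, 169 and 204 FPKM in WT replicates 1 to 3 and at 164, 166 and 187 FPKM in the libraries labelled cKO. The means were 185 ± 17.8 FPKM in WT and 172 ± 12.7 FPKM in the libraries labelled cKO (SD, n = 3 each), a log2 fold change of -0.097 (SE 0.086, adjusted p = 0.707). The libraries labelled cKO held 93.4% of the WT level, with a 95% interval of 81.6% to 107%. The level was 73.2% of WT, with an interval of 55.7% to 96.1%, with the Y-linked share as a covariate, added after the data were seen (log2 fold change -0.45, adjusted p = 0.921), and against WT replicate 3 alone it was 84.4% with an interval of 70.1% to 102%. An exact permutation test of the 6 values gave a two-sided p of 0.5, where 0.1 is the smallest that 3 against 3 libraries can give. The target transcript was thus not lost in the libraries labelled cKO, while a partial reduction stays open (unadjusted p = 0.0299 in limma with the covariate). Every direction below is one between WT and the libraries labelled cKO, not between cells with and without the gene. Whether the deleted part of the gene lies within what was counted is not given in the sources used here.

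**Figure D1:**
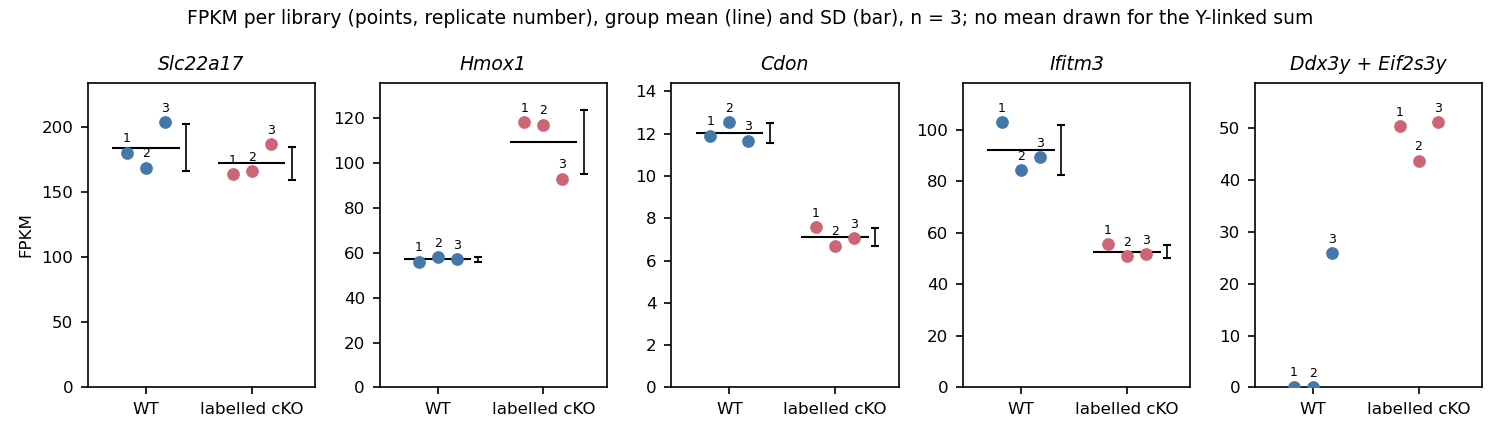
FPKM of Slc22a17, Hmox1, Cdon and Ifitm3 and the sum of the Y-linked genes Ddx3y and Eif2s3y, on linear axes from 0, in WT (blue) and in the libraries labelled cKO (red). Points are libraries with their replicate number, lines are means and bars are SD (n = 3 each, none drawn for the Y-linked sum). Slc22a17 overlaps between the groups at 164 to 204 FPKM, while Hmox1, Cdon and Ifitm3 do not overlap.

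Hmox1 rose in the libraries labelled cKO, and Cdon and Ifitm3 fell. Hmox1 (identifier 15368, chromosome 8, 75093618 to 75100593), which encodes heme oxygenase 1, the enzyme that releases iron from heme, went from 57.1 ± 0.97 to 110 ± 14.2 FPKM (SD, n = 3 each), 1.92 times the WT mean (log2 fold change 0.92, SE 0.091, adjusted p = 0.0253). Cdon (identifier 57810, chromosome 9, 35421528 to 35507652), a cell surface co-receptor for Sonic hedgehog, was at 12.04 ± 0.45 FPKM in WT and 7.11 ± 0.43 FPKM in the libraries labelled cKO (log2 fold change -0.69, SE 0.069, adjusted p = 0.0253). Ifitm3 (identifier 66141, chromosome 7, 141009590 to 141010744), an interferon-induced membrane protein, was at 92.1 ± 9.61 and 52.7 ± 2.47 FPKM (log2 fold change -0.79, SE 0.080, adjusted p = 0.0253). WT replicate 3, the WT library with Y-linked transcripts, was at 57.1 FPKM for Hmox1, 11.7 for Cdon and 89.2 for Ifitm3. These 3 genes, 1 higher and 2 lower, were all that passed an adjusted p of 0.05 in limma. At an unadjusted p under 0.05 there were 515 higher and 907 lower genes, 1422 in all. Uniform p-values would give 579.8. Of the divisions that mixed the groups, WT replicates 1 and 2 with cKO replicate 2 against the rest gave the most, 1291. The remaining mixed divisions gave 236 to 707. The WT and cKO values did not overlap for 17.2% of genes, where chance gives 10% for 3 against 3.

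Each of these calls was lost without certain single libraries, while the log2 fold changes stayed at 0.86 to 1.03 for Hmox1, -0.73 to -0.65 for Cdon and -0.85 to -0.71 for Ifitm3. Hmox1 missed the threshold without WT replicate 1 (adjusted p = 0.187), WT replicate 2 (adjusted p = 0.0933), cKO replicate 1 (adjusted p = 0.122) or cKO replicate 2 (adjusted p = 0.0887). Cdon missed it without any of the same 4 libraries (adjusted p = 0.192, 0.0966, 0.122 and 0.0887) or without cKO replicate 3 (adjusted p = 0.107). Ifitm3 missed it without WT replicate 1 (adjusted p = 0.179), cKO replicate 1 (adjusted p = 0.122), cKO replicate 2 (adjusted p = 0.0887) or cKO replicate 3 (adjusted p = 0.107). The number of genes past the threshold was 0 without WT replicate 1, 2 without WT replicate 2, 10 without WT replicate 3, 0 without cKO replicate 1, and 1 without cKO replicate 2 or 3. The 10 without WT replicate 3, the only WT library with Ddx3y and Eif2s3y transcripts, included the sex-linked genes Ddx3y (adjusted p = 1.61e-06), Eif2s3y (adjusted p = 1.58e-06) and Eif2s3x (adjusted p = 0.0295). With the Y-linked share as a covariate, an analysis added after the data were seen, no gene passed and the 3 genes had log2 fold changes of 0.99, -0.63 and -0.73, each with an adjusted p of 0.921.

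The genes of next lowest p, which did not pass (adjusted p = 0.103 each), included markers of quiescent stem cells and astrocytes. Hopx, a homeodomain protein of quiescent radial glia-like cells, averaged 5.97 FPKM in WT and 18.1 FPKM in the libraries labelled cKO, with a log2 fold change of 1.46. Gjb6, the astrocyte gap junction protein connexin 30, averaged 13.6 and 22.5 FPKM. Gnao1, a G protein subunit, averaged 47.0 and 67.8 FPKM, and Rab11fip4, a Rab11 effector, 6.83 and 9.91 FPKM. On the other side stood Bst2, an interferon-induced antiviral protein, at 8.23 and 5.13 FPKM, Igfbp4, a binding protein of insulin-like growth factors, at 229 and 154 FPKM, and Tagln2, an actin-binding protein, at 39.9 and 22.2 FPKM. All 7 genes had non-overlapping values, as did 17.2% of all tested genes. All 7 passed with library weights, Hopx with an adjusted p of 0.0144. That setting called 129 genes, the sex-linked Ddx3y, Eif2s3y and Eif2s3x among them. Without WT replicate 3 Hopx (adjusted p = 0.0376) and Tagln2 (adjusted p = 0.0444) passed, while with the Y-linked share as a covariate the log2 fold change of Hopx was 0.44 (adjusted p = 0.921).

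Among genes of iron handling, only Hmox1 passed. The ferritin chains, which store iron, had higher values in each of the libraries labelled cKO than in any WT library but did not pass. Ftl1 averaged 758 ± 26.3 and 965 ± 104 FPKM (log2 fold change 0.34, adjusted p = 0.238). Fth1 averaged 2011 ± 38.2 and 2534 ± 610 FPKM (log2 fold change 0.31, adjusted p = 0.483). Its mean in the libraries labelled cKO rested mostly on replicate 2. Fth1 stood at 2046, 2018 and 1970 FPKM in WT replicates 1 to 3 and at 2075, 3226 and 2301 FPKM in cKO replicates 1 to 3. The transferrin receptor Tfrc averaged 30.0 ± 8.48 and 28.0 ± 2.40 FPKM (log2 fold change -0.060, adjusted p = 0.929). Lcn2, the ligand of the Slc22a17 receptor, averaged 2.75 ± 1.26 and 3.07 ± 1.77 FPKM (adjusted p = 0.953), and the iron exporter Slc40a1 was below the filter with a mean of 0.17 FPKM. Of the 31 tested iron handling genes 17 had higher and 14 lower means, 1 passed adjusted over the list alone, and the list did not pass by camera (adjusted p = 0.296). By mixed fry, which counts changes in either direction and here includes Hmox1, the list passed (adjusted p = 0.0125). The list was not tested by mixed fry without Hmox1. By camera it passed as higher with the Y-linked share as a covariate (adjusted p = 0.0112, adjusted p = 0.577 with an estimated correlation) and against WT replicate 3 alone (adjusted p = 0.0265, adjusted p = 0.687 with an estimated correlation). Transcripts that increase when iron is scarce were mostly lower, with 8 of 9 lower and a median log2 fold change of -0.16 (adjusted p = 0.282). The WT libraries lay at both ends of that list, with WT replicate 2 the highest of the 6 libraries at 0.27 and WT replicate 3 the lowest at -0.32. The list passed without WT replicate 3, with a median of -0.29 (adjusted p = 0.00910, adjusted p = 0.585 with an estimated correlation). Its median was -0.26 with library weights and -0.099 without cKO replicate 2. The median was -0.079 without WT replicate 1, -0.023 without WT replicate 2 and 0.044 against WT replicate 3 alone. This list was higher with the Y-linked share as a covariate, with a median of 0.38 and 2 of 9 lower (adjusted p = 0.00209, adjusted p = 0.577 with an estimated correlation). Heme and iron-sulfur cluster genes had a median of -0.0057, a mean of -0.020 and an upward sign in the test relative to all other genes (adjusted p = 0.895).

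Genes of ferroptosis control and antioxidant defence were higher as a group. Of 32 tested members 22 had higher means in the libraries labelled cKO, with a median log2 fold change of 0.12 (adjusted p = 5.57e-05 by camera with its preset correlation, adjusted p = 0.536 with an estimated correlation). The median was 0.059 without WT replicate 2 and 0.053 without cKO replicate 2. Besides Hmox1, catalase (Cat) averaged 61.2 and 77.4 FPKM, Gclm, the modifier subunit of the first enzyme of glutathione synthesis, 42.3 and 54.5 FPKM, and Srxn1, which repairs oxidised peroxiredoxins, 23.2 and 30.9 FPKM. Hmox1 alone passed over all genes, and 3 members passed adjusted over the list alone. The cystine carrier Slc7a11 averaged 9.22 ± 1.00 and 13.0 ± 3.13 FPKM (adjusted p = 0.297), and the lipid peroxide reductase Gpx4, the central brake on ferroptosis, 184 ± 14.2 and 190 ± 4.98 FPKM (adjusted p = 0.849).

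Astrocyte markers were also higher as a group, with 14 of 20 means higher and a median log2 fold change of 0.16 (adjusted p = 0.000239, adjusted p = 0.661 with an estimated correlation). The list missed the threshold with the Y-linked share as a covariate (median 0.10, adjusted p = 0.0743), and its median was 0.097 without cKO replicate 3 and 0.10 with quantile normalization. Sparcl1, a secreted glycoprotein, averaged 526 and 757 FPKM, and the growth factor receptor Fgfr3 averaged 55.8 and 65.4 FPKM. Cd44, an adhesion receptor of immature astrocytes, went the other way, at 17.8 and 13.4 FPKM. Adjusted over the list alone 7 markers passed as higher and 1 as lower, and over all genes none passed. Gfap was at 2281 ± 558 and 2442 ± 51.2 FPKM (adjusted p = 0.823), and its sign turned without WT replicate 2 (log2 fold change -0.084).

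Cell cycle genes had lower means in the libraries labelled cKO. In the mitosis list 44 of 45 genes had lower means, with a median log2 fold change of -0.39 (adjusted p = 6.34e-20, adjusted p = 0.713 with an estimated correlation, which was 0.87 between members). Birc5, a regulator of chromosome segregation, averaged 30.9 and 20.9 FPKM, Top2a, the topoisomerase of dividing cells, 62.1 and 44.1 FPKM, and the mitotic kinesin Kif2c 11.3 and 8.27 FPKM. The proliferation marker Mki67 averaged 29.2 ± 4.55 and 21.2 ± 3.03 FPKM (adjusted p = 0.242). All 44 DNA replication genes had lower means, with a median of -0.25 (adjusted p = 7.53e-13, adjusted p = 0.713 with an estimated correlation). Among them Lig1, the replicative DNA ligase, averaged 20.1 and 14.98 FPKM, and Rfc4, a subunit of the clamp loader, 12.3 and 10.1 FPKM. No gene of either list passed over all genes, while adjusted over the list alone 40 mitosis genes passed as lower and 1 as higher (Tubb4b, a tubulin named after its values were seen, at 247 and 286 FPKM), and 11 replication genes as lower. Relative to the WT mean, the mitosis genes stood on average at -0.42, -0.56 and -0.15 on the log2 scale in cKO replicates 1 to 3 and at -0.13, 0.17 and -0.043 in WT. The replication genes stood at -0.28, -0.37 and -0.048 in cKO replicates 1 to 3 and at -0.048, -0.017 and 0.065 in WT, so that cKO replicate 3 was level with WT replicate 1. The mitosis median was -0.24 with library weights, and the replication median was -0.50 with the Y-linked share as a covariate.

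Immediate early genes, which respond within minutes to growth factors and to handling, were lower for 18 of 20 members, with a median log2 fold change of -0.36 (adjusted p = 1.04e-07, adjusted p = 0.679 with an estimated correlation). Fos averaged 31.7 and 13.1 FPKM, Junb 20.02 and 8.43 FPKM, Egr1 75.6 and 50.04 FPKM, and Dusp1 10.7 and 6.11 FPKM. None passed over all genes and 6 passed adjusted over the list alone. WT replicate 3 lay between, at -0.23 relative to the WT mean, and with the Y-linked share as a covariate the sign of the list turned, with a median of 0.080 (adjusted p = 0.373). The median was -0.58 with library weights and -0.21 against WT replicate 3 alone.

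Hypoxia response genes had lower means for 37 of 41 members, with a median of -0.34 (adjusted p = 5.98e-05, adjusted p = 0.740 with an estimated correlation), but the WT libraries lay apart. On average the members stood at 0.11, 0.39 and -0.50 on the log2 scale in WT replicates 1 to 3, and at -0.49, -0.065 and -0.46 in the libraries labelled cKO. Hilpda, a lipid droplet protein, averaged 19.1 and 12.6 FPKM, and Car12, a carbonic anhydrase, 3.00 and 1.91 FPKM. No member passed over all genes, and 2 passed adjusted over the list alone, both lower. Its median was -0.59 without WT replicate 3 and -0.11 without WT replicate 2, where the list missed the threshold (adjusted p = 0.0662). Against WT replicate 3 alone the median was 0.16, the opposite sign (adjusted p = 0.000564, adjusted p = 0.794 with an estimated correlation), and with the Y-linked share as a covariate it was 0.80 (adjusted p = 6.00e-25, adjusted p = 0.577 with an estimated correlation).

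Ribosomal protein genes had lower means by a small amount, in 77 of 78 genes with a median of -0.14 (adjusted p = 2.49e-11, adjusted p = 0.740 with an estimated correlation). On average they stood at -0.19, -0.026 and -0.18 in cKO replicates 1 to 3 and at -0.075, 0.079 and -0.0040 in WT, so that cKO replicate 2 lay above WT replicate 1. Rpl24 averaged 365 and 312 FPKM and Rps6 315 and 274 FPKM. None of them passed, adjusted over all genes or adjusted over the list alone, and with the Y-linked share as a covariate the median was -0.048, with 59 of 78 lower (adjusted p = 0.1498). With library weights the median was -0.079. Interferon-stimulated genes were lower for 24 of 27 members, with a median of -0.12 (adjusted p = 0.00705, adjusted p = 0.740 with an estimated correlation). The immunoproteasome subunits Psmb9 and Psmb8 averaged 2.47 and 1.40 FPKM and 2.76 and 1.91 FPKM, and Bst2 alone passed adjusted over the list alone. Ifitm3 is not a member of that list. The interferon list was higher with the Y-linked share as a covariate, with a median of 0.29 and 7 of 27 lower (adjusted p = 0.00209, adjusted p = 0.577 with an estimated correlation), and WT replicate 3, at -0.13 relative to the WT mean, lay below cKO replicate 2 at 0.0068. Matrix and adhesion genes were lower for 24 of 33 members, with a median of -0.13 (adjusted p = 0.0204, adjusted p = 0.713 with an estimated correlation) and none past adjusted over the list alone. Tnc, a matrix glycoprotein of the stem cell niche, averaged 4.15 and 2.57 FPKM, and the laminin receptor subunit Itga7 18.4 and 14.9 FPKM. Without WT replicate 1 the interferon list had an adjusted p of 0.164 and the matrix list one of 0.116. Without cKO replicate 1 both had an adjusted p of 0.0803, and without cKO replicate 3 the interferon list had one of 0.0902. The interferon median was -0.062 without WT replicate 1, -0.20 without WT replicate 3 and -0.18 without cKO replicate 2. Both lists also missed the threshold with a minimum mean of 5 FPKM (adjusted p = 0.141 and 0.156) and against WT replicate 3 alone (adjusted p = 0.995 and 0.487, medians 0.0059 and -0.023). The matrix list missed it without genes on X and Y (adjusted p = 0.107) and with the Y-linked share as a covariate, where its median was 0.039 (adjusted p = 0.369).

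Markers of neural stem cells and of neurons did not pass as groups in the main test, which does not show that they were unchanged. Stem cell and radial glia markers had 21 of 32 means lower, with a median of -0.065 (adjusted p = 0.641), and 1 of them, Hopx, passed adjusted over the list alone. Tnc, the member of next lowest p, is also in the matrix list, and Hes1, a target of NOTCH signalling, averaged 11.9 and 9.73 FPKM. Sox2 averaged 135 ± 11.8 and 128 ± 7.77 FPKM (adjusted p = 0.761), and the intermediate filament nestin (Nes) 104 ± 20.03 and 92.1 ± 15.6 FPKM (adjusted p = 0.733). Of 43 neuronal lineage markers 33 were in the table, and only 15 reached the filter and were tested. Of these 15 markers 7 had higher and 8 lower means, with a median of -0.0019 (adjusted p = 0.835). With median-ratio scaling the median was 0.018 (adjusted p = 0.773). Adjusted over the list alone 2 passed, both lower: Cd24a, a surface protein of neuroblasts, at 32.4 and 23.9 FPKM, and the microtubule regulator Stmn1 at 208 and 167 FPKM. Tubb3, the neuronal tubulin, was at 4.02 ± 0.54 and 5.15 ± 0.23 FPKM (adjusted p = 0.279), and the neuroblast marker Dcx was below the filter with a mean of 0.20 FPKM. Without cKO replicate 1 the neuronal list passed as lower (adjusted p = 0.0435, adjusted p = 0.573 with an estimated correlation).

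**Figure D2:**
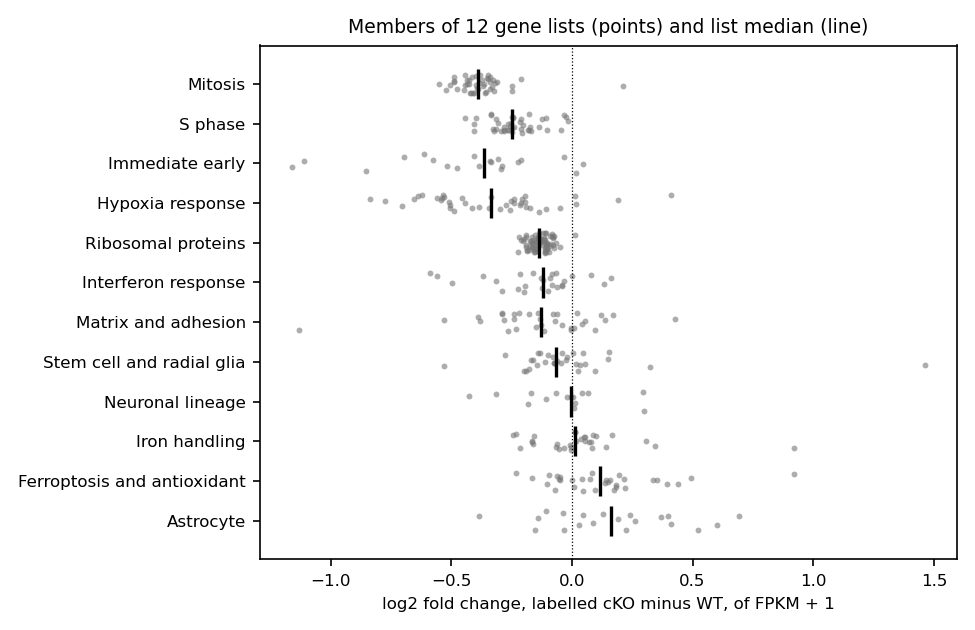
Log2 fold change between the libraries labelled cKO and WT, on the log2(FPKM + 1) scale, of every tested member of 12 gene lists (points), with the list median (line). Mitosis genes centre on -0.39 and astrocyte markers on 0.16, and the single point at 1.46 among stem cell markers is Hopx.

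Of the 29 lists tested, 9 passed with the preset correlation, 2 higher and 7 lower, and none of the 9 held with an estimated correlation (smallest adjusted p = 0.536). The other 9 ways of dividing the 6 libraries into 3 and 3 gave from 8 to 14 lists past the same threshold.

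**Figure D3:**
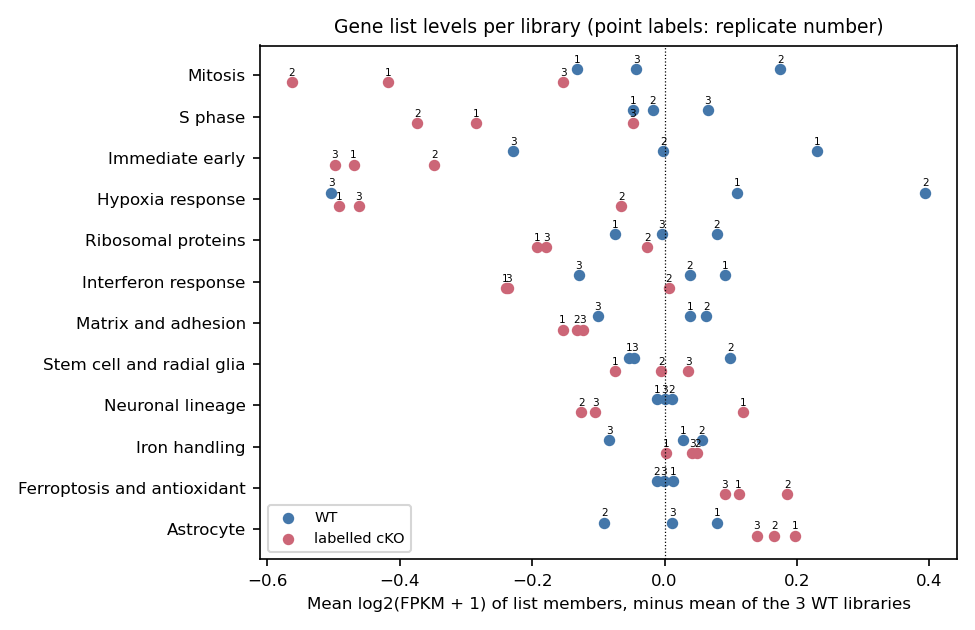
Mean log2(FPKM + 1) of the members of 12 gene lists in each library, relative to the mean of the 3 WT libraries, with WT in blue, the libraries labelled cKO in red and the replicate number above each point. The hypoxia genes of WT replicate 3, at -0.50, lie below those of every other library, with cKO replicate 1 next at -0.49. The ferroptosis and antioxidant genes of the libraries labelled cKO, at 0.091 to 0.19, lie above all WT libraries.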

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

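The tests with the Y-linked share, without WT replicates 1 and 2, and without genes on X and Y were chosen after the data were seen, as were the estimated correlations given for settings other than the main one. Slc22a17 kept its negative sign and missed the threshold under every alternative run, with log2 fold changes from -0.45 to -0.023 and adjusted p of 0.487 to 0.999. Hmox1, Cdon and Ifitm3 kept their signs under all of them, with log2 fold changes of 0.86 to 1.03, -0.76 to -0.63 and -0.92 to -0.71. Their adjusted p ranged from 0.00402 to 0.999. All 3 stayed past the threshold with either other pseudocount, a minimum mean of 5, median-ratio scaling, robust hyperparameters, library weights, the replicate block and without genes on X and Y. A count model on recovered whole reads was not run, since only 43.1% to 56.9% of the low values lay within 0.1 fragment of a whole multiple. The depth estimate rests on few low values and sets no limit on single genes.

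There were 0 higher and 0 lower genes with no filter, with quantile normalization, with no intensity trend, with the Y-linked share as a covariate, and against WT replicate 3 alone, where the lone WT library is assumed to vary like the others. The smallest adjusted p there was 0.0699, 0.0590, 0.0887, 0.369 and 0.258, and 1610, 1473, 1381, 549 and 421 genes had an unadjusted p under 0.05. Without a filter more genes were tested, and the last setting has fewer libraries. With the covariate the errors widened, since it nearly follows the group (correlation 0.91). For quantile normalization and no trend the cause was not tested. Values scaled to a common sum left 1 higher and 1 lower gene, without Cdon. Library weights gave 54 higher and 75 lower genes, and an unadjusted p under 0.05 gave 515 and 907. Leaving out 1 library gave 0 to 4 higher and 0 to 6 lower genes. At an adjusted p under 0.10 the counts were 1 and 2.

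Whether the replicate numbers pair the libraries could not be told. Correlations of same-numbered deviations were -0.043, 0.30 and 0.26. WT replicates 2 and 3 each went best with the cKO library of the same number, while WT replicate 1 went best with cKO replicate 2. With the replicate number as a block there were 9 higher and 13 lower genes, the same 3 and Hopx (adjusted p = 0.000543) among them.

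The number of lists past the threshold was 0 with an estimated correlation, 0 with directional fry (5 at an unadjusted p under 0.05) and 4 with mixed fry (iron handling, antioxidant, astrocyte and target neighbour lists, adjusted p = 0.0125 each), and 8 to 14 when 1 library was left out. Other medians that moved by over 1.5 times included those of the matrix list without a filter (-0.079) and the interferon list with a minimum mean of 5 (-0.074). Without WT replicate 2 the stem cell median was -0.0066, and without cKO replicate 1 the neuronal median was -0.10. List members past the threshold numbered 81 adjusted over the list alone.

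A list's direction is here that of camera, relative to all other genes, and its median can keep its sign where this turns. None of the described lists passed with an estimated correlation in any setting run (smallest adjusted p = 0.253). Signs that turned belonged to genes that had not passed over all genes and to lists that had not passed, except for 4 lists. With the Y-linked share as a covariate the hypoxia (adjusted p = 6.00e-25), interferon (adjusted p = 0.00209), immediate early (adjusted p = 0.373) and matrix (adjusted p = 0.369) lists turned upward. So did iron scarcity (adjusted p = 0.00209), stem cell (adjusted p = 0.458) and oligodendrocyte (adjusted p = 0.961) lists. Log2 fold changes that turned there were Tfrc 0.96, Sox2 0.21, Gfap -0.16, Gpx4 -0.086, Slc7a11 -0.054, Tnc 0.036, Itga7 0.071, Col4a6 0.21, Aldoc -0.016, Adm 0.40, Junb 0.33, Kdm6a 0.078, Kdm5c 0.072, Egln3 1.27, Plod2 0.69, Elavl4 -0.22, Cnp 0.040 and Cmtm5 -0.052. Against WT replicate 3 alone the lists that turned were hypoxia (adjusted p = 0.000564), iron scarcity (adjusted p = 0.265), stem cell (adjusted p = 0.733) and oligodendrocyte (adjusted p = 0.615, with stem cell and oligodendrocyte medians of -0.0072 and -0.018), and the genes Tfrc 0.39, Sox2 0.032, Gfap -0.00049, Gpx4 -0.024, Egln3 0.15 and Plod2 0.024. The interferon median was 0.0059 there, with its direction kept. Library weights turned Gfap (-0.088), Gpx4 (-0.012) and the directions of the stem cell (adjusted p = 0.951) and oligodendrocyte (adjusted p = 0.736) lists, whose medians stayed negative (-0.019 and -0.013). The cause was not tested.

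Leaving out 1 library turned the sign of Tfrc, Gfap, Gpx4 and Lcn2, with ranges of -0.29 to 0.12, -0.084 to 0.28, -0.020 to 0.079 and -0.23 to 0.43. It also turned the directions of the stem cell (medians all negative), neuronal and oligodendrocyte lists, with adjusted p of 0.441 to 0.987, 0.0435 to 0.961 and 0.0303 to 0.744.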

Other observations

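The tests of the retained Slc22a17 transcript, of the sex of the libraries and of WT replicate 2 were chosen after the results they bear on had been seen. The divisions of the libraries and the test of further antioxidant targets were set before their results were seen, the latter on a list written after Hmox1 had been seen to rise.

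Among genes of the oligodendrocyte lineage, those of lowest p encode proteins of myelin. Mobp averaged 5.52 FPKM in WT and 3.17 FPKM in the libraries labelled cKO, Mag 7.17 and 4.65 FPKM, Mog 2.80 and 1.79 FPKM, and Cnp 155 and 136 FPKM. Gpr17, a marker of committed precursors named after its values were seen, was at 3.37, 30.3 and 4.53 FPKM in WT and at 13.8, 19.5 and 16.1 FPKM in the libraries labelled cKO. Of the 21 tested genes of the oligodendrocyte lineage none passed, adjusted over all genes or adjusted over the list alone, and the list did not pass (adjusted p = 0.337). The direction depended on which WT library was left out, with WT replicate 1 at -0.27 and WT replicate 2 at 0.38 relative to the WT mean. Without WT replicate 1 the list passed as lower (adjusted p = 0.0303, adjusted p = 0.748 with an estimated correlation). Without WT replicate 2 its median was 0.0010 (adjusted p = 0.154), and Gpr17 passed as higher (log2 fold change 1.82, adjusted p = 0.0388). Microglial genes were present at low levels, with complement C1qa, also named after its values were seen, at 5.34, 6.20 and 5.13 FPKM in WT and 2.85, 6.11 and 6.76 FPKM in the libraries labelled cKO.

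Some genes next to Slc22a17 on chromosome 14 differed in small steps in both directions. Efs, an adaptor protein of adhesion signalling, averaged 31.1 and 24.3 FPKM, Pabpn1, the nuclear poly(A) binding protein, 136 and 117 FPKM, and Cmtm5, a membrane protein of myelinating cells, 84.1 and 104 FPKM. All 3 had non-overlapping groups and an adjusted p of 0.0241 adjusted over the list alone, 1 higher and 2 lower, and none passed over all genes. As a group the 13 tested neighbours did not pass by the tests of a shared direction (adjusted p = 0.641 by camera and 0.0845 by fry), and passed by mixed fry, which counts changes in either direction (adjusted p = 0.0125). Among genes of iron-dependent dioxygenases the 2 of lowest p were the X-linked demethylases Kdm6a and Kdm5c, at 6.86 and 4.43 FPKM and at 17.3 and 13.2 FPKM. Of these, Kdm6a alone passed adjusted over the list alone. In WT replicate 3 Kdm6a and Kdm5c stood at 5.53 and 14.8 FPKM, between the other WT libraries and the libraries labelled cKO, as Eif2s3x did. With the Y-linked share as a covariate their log2 fold changes were 0.078 and 0.072. For these 2 genes the label and the Y-linked share cannot be told apart.

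The Slc22a17 transcript was retained in the libraries labelled cKO. The lower end of the 95% interval, 81.6% of WT and 55.7% with the Y-linked share as a covariate, argues against loss of the whole transcript in most cells. A swap of libraries between the groups stays open, because no library was low (the lowest WT library stood at 82.9% of the highest of all 6), so that a swapped one would look the same. A deletion of some exons that leaves a transcript may account for a mean at 93.4% of WT, and it cannot be told apart from an intact gene because values per exon were not analysed here. A gene that was never deleted in these cultures stays open for the same reason.

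Hmox1, Cdon and Ifitm3 separated the groups without overlap. With the Y-linked share as a covariate the smallest adjusted p of the 3 was 0.921, while their log2 fold changes went from 0.92 (SE 0.091), -0.69 (SE 0.069) and -0.79 (SE 0.080) to 0.99 (SE 0.23), -0.63 (SE 0.18) and -0.73 (SE 0.20). The calls ended because the covariate and the group were nearly the same division of the libraries (correlation 0.91), which widened the errors. WT replicate 3, with 53.4% of the Y-linked level, had gone 0.12%, 8.86% and 7.52% of the way from the other WT libraries to the libraries labelled cKO for Hmox1, Cdon and Ifitm3, but 1 library decides nothing, so sex and genotype cannot be told apart for these genes. The real division called 3 genes and the highest of the other 9 called 0, and 10 divisions are too few for a share under 0.05.

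The mitosis and S phase genes had lower means in the libraries labelled cKO. Without WT replicate 2, the library farthest out on the first principal component, the mitosis median was -0.29, which argues against that library as the whole cause. With the Y-linked share as a covariate the median was -0.41 and the list stayed past the threshold with the preset correlation (adjusted p = 5.03e-08), while with an estimated correlation the adjusted p was 0.685 with the covariate and 0.713 without it. The mean level of the list differed by -0.40 with the covariate (95% interval -1.75 to 0.95) and by -0.38 without it (-0.80 to 0.040), so the covariate did not remove the difference, but its interval is too wide to tell the sex of the libraries apart from the label. The mitosis median lay 0.39 from 0 in the real division and at most 0.36 in the other 9, the real division called 9 lists and the others up to 14, and 10 divisions are too few for a share under 0.05.

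Hmox1 is a target of the transcription factors NRF2 and BACH1, and a candidate explanation for its rise is a wider response of their targets. Of 25 tested targets outside the lists fixed before, 21 had higher means, with a median log2 fold change of 0.083. None passed, and as a group they had a p of 3.61e-05 by camera with the preset correlation and 0.105 with an estimated correlation. The direction goes with the hypothesis, but the test does not decide it.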
